A study of Auxenochlorella pyrenoidosa with 18 samples.

How the data were processed

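The study sequenced messenger RNA libraries of the green alga Auxenochlorella pyrenoidosa, strain FACHB-9, a microalga that can grow on glucose in the dark or on light. The labels place 18 libraries in 6 groups of 3: heterotrophic cells at 0, 24 and 72 h and cells in the light at 2, 8 and 24 h. Per the labels' protocols, RNA was isolated with TRIzol, cleaned on columns and made into libraries with an Illumina TruSeq kit. The submitters' processing notes name TopHat 1.3.3 and Cufflinks. Read counts and expression values of the libraries were not analysed here, so the depth of each library is unknown here and no comparison between the 6 groups was made.

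The file analysed here is a set of predicted gene models for the whole series. Its 345615 lines name AUGUSTUS, a program that predicts genes from genome sequence, as their source. The version of AUGUSTUS, its settings, the evidence it was given and the version of the assembly are not given in the sources used here. The models give the position of genes, transcripts, exons, coding segments, introns, start and stop codons and transcript ends on the scaffolds, with coordinates that count from 1. Gene, transcript, coding segment and intron lines also carry the score that AUGUSTUS wrote, as deposited by the authors without a description. Of 185638 scored coding segment and intron lines, 943 had a score above 1, up to 2, so the scores were not treated as probabilities. The models belong to the series and to no library. The attributes hold identifiers and parents only, so the files do not pair the models with gene names or products, and the lists of photosynthesis, starch, lipid and nitrogen genes fixed for the study could not be applied. No genome sequence was used here, so splice sites, base composition and protein sequences were not analysed here.

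The models were read with Python 3.11.15 and analysed with NumPy 2.4.6, SciPy 1.17.1 and numba 0.67.0. Each gene was represented by its transcript with the longest coding sequence. Introns were taken as the gaps between neighbouring coding segments of that transcript, and the phase of an intron was read from the deposited phase of the coding segment after it. The annotated span of a scaffold ran from its first to its last gene model. Except for the shares given with a 95% Wilson interval, which counts models or introns as independent, each 95% interval came from 1000 resamplings of whole scaffolds, since neighbouring genes are not independent. The resampled intervals cover the spread between scaffolds of this annotation and no error of sequencing, assembly or prediction. First and later introns were compared within genes of at least 3 coding introns, on log2 lengths, with a two-sided test that flipped the sign of each gene's difference. The strands of neighbouring genes were tested two-sided by shuffling strands among the genes of each scaffold with at least 5 genes. The distances between divergent and convergent neighbours were compared on log2(distance + 1) with a two-sided permutation of the orientation labels. Each of these tests used 100000 permutations, and the smallest p they can give is 1e-05. The intron and distance tests treat genes or pairs as independent, so their p-values, unlike the resampled intervals, make no allowance for dependence between neighbours. Phase shares, exon symmetry, intron position and the correlation across genes were judged by whether the 95% interval excluded the value under no effect. Gene density was taken over scaffolds of at least 50 kb.

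The tests and their alternatives were fixed before the data were examined, with expression tests that were to run only if values per library were held. Some descriptions in the Results were not part of that plan, such as the same-strand share by distance and intron length by order. The fixed rule for named models took the 5 with the most exons, the 5 with the longest coding sequence, the 5 with the longest intron and the 3 scaffolds with the most genes. The alternatives fixed beforehand numbered 11 (scaffolds of at least 100 kb, coding lengths that are a multiple of 3, no overlapping models, coding lengths of at least 300 bases, leaving out the scaffold with the most genes, every transcript, coding segments in place of exons, introns of 30 to 2000 bases, introns between all exons, scaffolds with at least 20 genes, and distances between coding ends). A further 2 were chosen after seeing the data: complete models, and models with a mean coding score of at least 0.95. The code was tested on simulated models with known answers. In 6000 simulated genes with known effects, 6 of 6 intervals held the true value, and in 6000 without effects 5 of 6 did. The miss was the phase share, so 40 further sets without effects were drawn, and the interval held the true share in 39 of them. The simulated scaffolds all held the same number of genes, with phases and lengths drawn independently. Of the 1231 scaffolds analysed here, 888 held 1 gene, so the simulations do not show how well the intervals cover at such uneven sizes.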

Results

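The series followed Auxenochlorella pyrenoidosa from growth on glucose to growth in light, with 3 heterotrophic and 3 phototrophic time points of 3 libraries each. The values analysed here describe the predicted gene models of the alga, and no change of expression between the 6 groups is reported. The annotation held 10284 gene models with 10451 transcripts on 1231 scaffolds. The plus strand carried 5123 of the models. More than 1 transcript was predicted for 162 genes. A start codon and a stop codon were both present in 8901 models (86.6%), and the coding length of all 8901 was a multiple of 3.

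Complete models lay mainly on scaffolds with a long annotated span. The 29 scaffolds with an annotated span of 500 kb and over carried 7270 models (70.7% of all), of which 99.7% were complete (95% Wilson interval 99.5 to 99.8%). The 1128 scaffolds with a span under 5 kb carried 1381 models, of which 7.82% were complete (95% Wilson interval 6.52 to 9.36%). Mean exon number was 10.4 ± 7.61 (SD, n = 7270) on the former and 5.21 ± 2.44 (SD, n = 1381) on the latter. On the 888 scaffolds with 1 gene the annotated span is the length of that gene model. The class under 5 kb therefore favours short models by construction, and the full length of the scaffolds is unknown here. The scaffolds with the most genes were scaffold00366 (691 genes between bases 2172 and 3904654), scaffold01012 (548 genes, bases 1 to 2954257) and scaffold00012 (474 genes, bases 1 to 2794055). Over the 63 scaffolds of at least 50 kb, 8802 genes on 52561706 bases gave a density of 16.7 genes per 100 kb (95% interval 16.3 to 17.1).

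Genes of this alga were predicted with many exons and almost none without an intron. The mean was 9.64 exons per gene (95% interval 9.29 to 9.90, n = 10284 genes), with a median of 8 and a 5th to 95th percentile range of 3 to 24. Single-exon models without an intron numbered 66, a share of 0.642% (95% interval 0.402 to 0.948%). Counted by coding segments, 141 models had no intron within the coding sequence, a share of 1.37% (95% interval 1.06 to 1.74%). Median coding length was 1038 bases (95% interval 994 to 1077). Coding length and exon number rose together across genes, with a Spearman rho of 0.78 (95% interval 0.77 to 0.79) and a Pearson r of 0.82. Genes are not independent replicates, and the interval comes from resampling scaffolds. Coding length is summed over the coding segments, so some positive relation follows from how it is measured. The internal coding exons were short, with a median of 107 bases (95% interval 106 to 109, n = 74992). Where transcript ends were predicted, the median 5' untranslated length was 74 bases (95% interval 73 to 76, n = 9209 genes) and the median 3' untranslated length was 147 bases (95% interval 144 to 152, n = 9407 genes). A whole untranslated exon, and so an intron in the untranslated part, was present at the 5' end of 25.4% of the 9209 models with a predicted 5' end (95% interval 24.5 to 26.5%), and at the 3' end of 3.39% of the 9407 models with a predicted 3' end (95% interval 3.0 to 3.7%).

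The models with the most exons were g8501 (103 exons, scaffold01168, bases 544400 to 575753, minus strand), g2357 (97 exons, scaffold00252, bases 114096 to 144620, plus strand), g257 (85 exons, scaffold00012, bases 1325196 to 1356249, minus strand), g8127 (79 exons, scaffold01094, bases 431772 to 465168, plus strand) and g1272 (74 exons, scaffold00092, bases 1186646 to 1227739, minus strand). The longest coding sequences were those of g1272 with 27831 bases, g5402 with 24915 bases, g1271 with 23100 bases, g8127 with 18072 bases and g8501 with 14331 bases. Model g5402 lay on scaffold00760 between bases 18156 and 58620 on the minus strand. Model g1271 lay on scaffold00092 between bases 1150116 and 1185049, next to g1272 and on the same strand. All of these models were complete. Each had a low gene score, between 0.01 and 0.04, against a median of 0.11 over all genes. The mean score of their coding segments lay between 0.906 and 0.975, on both sides of the mean of 0.941 over all coding segments. These models were chosen for their size, and whether the gene score falls with exon number was not examined.

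Introns were short and of similar length along most of the gene, and the first was shorter than the rest. The median coding intron measured 209 bases (95% interval 204 to 214, n = 85135), with a 5th percentile of 122 and a 95th percentile of 508 bases. In genes with at least 3 coding introns, the first had a median length of 195 bases and the later ones 210 bases. Within genes the first intron was 0.872 times as long as the later ones (95% interval 0.861 to 0.884, n = 8873 genes), a log2 difference of -0.20 (sign-flip permutation test, two-sided, p = 1e-05, the smallest it can give). The first intron was longer than the mean of the later ones, taken on log2 lengths, in 36.6% of these genes. Intron lengths are skewed, and this share was not tested against an expected value. In the 3996 complete models with at least 8 coding introns, the median rose from 189 bases at the first intron (95% interval 185 to 192) to 203 at the second (199 to 208) and 214 at the third (209 to 220), and the last intron measured 205 bases (200 to 211).

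**Figure D1:**
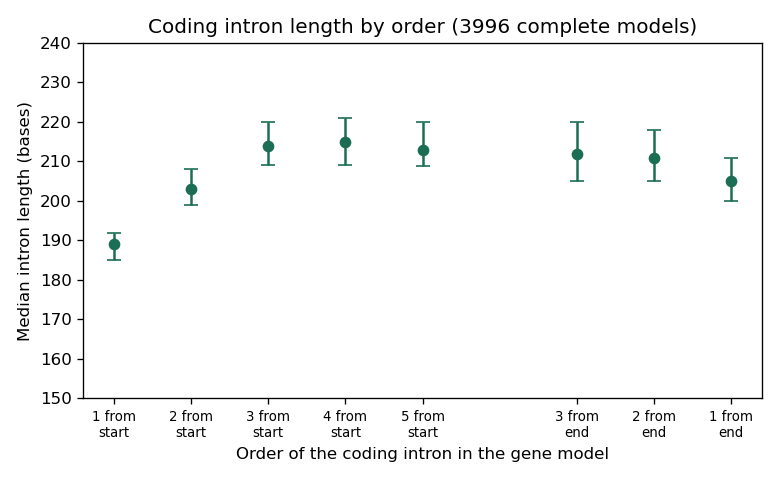
Median length in bases (vertical axis, starting at 150) of coding introns by their order from the start or the end of the coding sequence (horizontal axis), in 3996 complete models with at least 8 coding introns. Points are medians and bars are 95% intervals from resampling scaffolds; the first intron, at 189 bases, lies below the second, at 203, and the third, at 214.

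The 5 longest single introns measured 5653 to 6445 bases. Model g1532 (scaffold00128, bases 953558 to 966318, plus strand) held an intron of 6445 bases between bases 957201 and 963645. Model g9269 (scaffold01211, bases 1046436 to 1056330, plus strand) held one of 6405 bases between bases 1048412 and 1054816. The others were an intron of 5935 bases in g2985 (scaffold00366, bases 1203228 to 1209162), one of 5917 bases in g3779 (scaffold00514, bases 378716 to 384632) and one of 5653 bases in g8016 (scaffold01082, bases 147424 to 153076). AUGUSTUS gave the introns of g1532 and g9269 scores of 0.67 and 0.66, that of g2985 a score of 0.99 and those of g3779 and g8016 a score of 1.

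Introns lay between codons more often than equal shares of the 3 phases would give. Phase 0, between codons, held 49.7% of coding introns (95% interval 49.1 to 50.2%), phase 1 held 28.0% (27.4 to 28.5%) and phase 2 held 22.3% (22.0 to 22.7%), and the interval of phase 0 excluded the equal share of 1 in 3. Internal coding exons whose length was a multiple of 3 made up 38.4%, against 37.5% if the phases on either side were independent. The interval of the excess of 0.875 percentage points (95% interval 0.506 to 1.21) excluded 0. The expected share used phases pooled over all genes. Differences in phase use between genes could therefore also give an excess, and the test cannot tell this from dependence between neighbouring introns. Introns lay slightly nearer the start of the coding sequence, at a mean relative position of 0.480 (95% interval 0.478 to 0.483, n = 10143 genes) where 0.5 is the middle.

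Neighbouring genes tended to lie on opposite strands. On scaffolds with at least 5 genes, 36.1% of 8762 neighbouring pairs lay on the same strand (95% interval 34.7 to 37.6%), against 49.8% on average when strands were shuffled within scaffolds (permutation test, two-sided, p = 1e-05, the smallest it can give). The share depended on distance. It was 14.8% (95% interval 13.8 to 16.0%) for the 2152 pairs less than 200 bases apart, and 35.8% (33.5 to 38.2%) for the 2046 pairs 200 to 500 bases apart. It was 42.9% (40.6 to 45%) for the 1332 pairs 500 to 1000 bases apart and 43.5% (41.1 to 46.3%) for the 1519 pairs 1000 to 3000 bases apart. It was 51.1% (48.7 to 53.3%) for the 1702 pairs at least 3000 bases apart, where the interval included the mean of the shuffles.

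**Figure D2:**
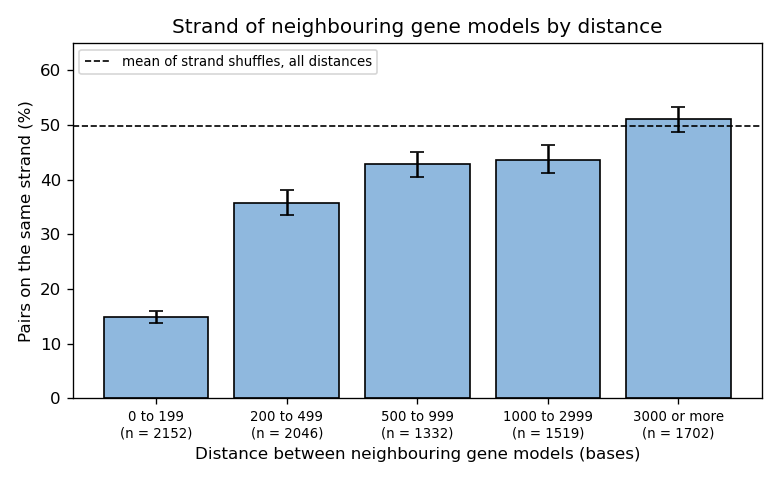
Share of neighbouring gene models on the same strand in percent (vertical axis) by the distance between them in bases (horizontal axis), with the number of pairs under each bar. Bars are shares, error bars are 95% intervals from resampling scaffolds, and the dashed line is the mean of the strand shuffles over all distances, 49.8%; the share is 14.8% below 200 bases and 51.1% from 3000 bases.

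The spacing of neighbours differed with their orientation. Median distance was 266 bases (95% interval 236 to 320) between the ends of 2913 convergent pairs, 465 bases (425 to 505) between the starts of 2888 divergent pairs, and 896 bases (815 to 985) between 3241 pairs on the same strand. The order was not the same over the whole range: the 25th percentile was 215 bases for divergent and 76 bases for convergent pairs, but the 75th percentile was 1215 bases for divergent and 1696 bases for convergent pairs. By the mean of log2 values, which gives weight to the shortest gaps, divergent pairs were 1.85 times as far apart as convergent pairs (95% interval 1.61 to 2.06; permutation test on log2 values, two-sided, p = 1e-05, the smallest it can give). Measured between coding sequences in place of transcript ends, the log2 difference was 0.00032 (95% interval -0.10 to 0.08; permutation test, two-sided, p = 0.993), so the call rests on the predicted untranslated ends. Gene models hardly overlapped, with 11 of 9053 neighbouring pairs doing so.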

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

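Of 58 values of tested results under the alternatives, 57 kept their direction and their side of the threshold, 1 lost its call and none reversed. This count includes 9 values of the correlation of coding length with exon number, which is positive in part by construction. It also includes alternatives that change little, such as leaving out overlapping models, which kept 10263 of 10284 models. Alternatives overlap as well: the 9498 models with coding lengths that are a multiple of 3 include all 8901 complete models. Of the 58, 7 lay outside the main 95% interval. Of 61 values of results without a test, 48 stayed within the main 95% interval and 13 moved outside it. The distance between divergent and convergent pairs lost its call between coding sequence ends, at 0.000321 log2 units; this alternative adds the untranslated ends to the gap, and the 3' ends (median 147 bases) are longer than the 5' ends (74 bases). Mean exons per gene was 10.4 on scaffolds of at least 100 kb, 9.98 with coding lengths that are a multiple of 3, 9.90 with at least 300 coding bases, 10.3 in complete models and 9.28 in coding segments; the first 4 of these leave models out and the last counts no untranslated exons. The share of genes without introns was 1.37% by coding segments. Median coding length was 1143 bases on scaffolds of at least 100 kb, 1086 with coding lengths that are a multiple of 3 and 1131 in complete models. With a mean coding score of at least 0.95 it was 963 bases. At that score the median 3' untranslated length was 161 bases and the median internal coding exon 105 bases. Gene density was 9.29 per 100 kb with a mean coding score of at least 0.95, which counts 5749 of the 10284 models. The same-strand share ranged from 35.4 to 36.3%, phase 0 from 49.6 to 50.4%, the first-intron difference from -0.22 to -0.14 log2 units and the exon symmetry excess from 0.845 to 0.934 percentage points. The expression tests, their alternatives and the functional gene lists were not run. No paired analysis was possible because the gene models carry no values of single libraries. Whether reads, and so their depth, shaped the predicted models is not given in the sources used here.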

Other observations

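The tests in this part were chosen after the gene models had been examined, except the same-strand share on scaffolds of at least 100 kb, which was fixed before. For 3 of the 6 explanations the outcome was predicted before the deciding value was seen: broken models on short scaffolds, incomplete models, and the score of introns that keep the reading frame. For broken and for incomplete models the outcome was fixed by how few values were left out. The same-strand share could have reached at most 36.3% and the share of short introns at most 29.3%, so these predictions could not fail.

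Some gene models shared the lengths of successive exons. In 55 pairs of gene models, 104 models in all, a run of at least 5 internal coding exons had identical lengths in the same order. Of these pairs, 35 (63.6%) lay on 1 scaffold, where 2.35% of all gene pairs do, and 19 (34.5%) were direct neighbours, 13 of them on the same strand. The longest shared run, 13 exons, joined g2180 (scaffold00230, bases 556781 to 567935) and g2182 (bases 578501 to 586845), and the next model, g2183 (bases 586993 to 591595), shared a run of 12 exons with each. Other neighbours were g4778 and g4779 on scaffold00629, with a run of 11 exons, and g6811 and g6812 on scaffold00992, with a run of 8. When the order of internal exons was shuffled within each model, 0 of 100 shuffles gave as many pairs and the highest count was 1, which argues against chance among similar exon lengths. Of 300 introns between shared exons, 4.33% had the same length in both models (95% Wilson interval 2.55 to 7.27%). The median absolute difference in length was 27 bases. For the pairs as a set, the low share argues against the same locus assembled more than once as identical copies. Introns were pooled over pairs, so the share cannot decide this for single pairs or for copies that differ in intron length. Some pairs on different scaffolds had a partner that began at base 1 of its scaffold, such as g1299 (scaffold00093, bases 1 to 4037). A candidate explanation for the pairs that lie close together on 1 scaffold is local gene duplication that kept exon lengths while the introns changed. It does not cover the pairs on different scaffolds. This is a hypothesis, found and tested on the same data, and protein sequences were not compared.

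The scarcity of neighbours on the same strand less than 3000 bases apart may have come from the prediction. Scaffolds of at least 100 kb held 8713 of the 8762 pairs, with a same-strand share of 36.1% (95% interval 34.7 to 37.5%), and the other 49 pairs are too few for models broken at the ends of short scaffolds to account for the pattern. Pairs at least 3000 bases apart had a share of 51.1% (95% interval 48.7 to 53.3%), as the joining of close same-strand neighbours into 1 model by the predictor would give. Among pairs without overlap, 3154 lay on the same strand and 5597 on opposite strands, a gap of 2443. Joining alone would have to hide about that many same-strand pairs if both kinds were equally frequent, and whether it did was not tested. A real preference for opposite strands that acts at short distance would give the same values and was not tested. The expression libraries were not used to look for joined models. Any joining would also have raised the exon number and coding length per gene model given above.

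Short introns were less often a multiple of 3 long than longer ones. Among 3753 coding introns under 120 bases the share was 28.0% (95% interval 26.4 to 29.7%), against 34.3% (33.5 to 35.0%) at 120 to 160 bases, 32.5% (31.6 to 33.4%) at 160 to 200 bases, 33.0% (32.3 to 33.7%) at 200 to 300 bases and 34.4% (33.6 to 35.2%) from 300 bases. In complete models the share was 27.7% (95% interval 26.1 to 29.3%), and these held 3582 of the 3753 introns, so the other 171 are too few for incomplete gene models to account for the pattern. The mean score of short introns a multiple of 3 long was 0.879, against 0.888 for the others, a difference of -0.0082 (95% interval -0.023 to 0.0057), too imprecise to say whether the predictor was less certain of short introns that keep the reading frame. The bin limits also shape the shares. Counts rose from 3753 introns under 120 bases to 14149 at 120 to 160 bases. In each 3 successive lengths counted down from just below 120, the multiple of 3 is the shortest. Where counts rise with length this lowers the share below 1 in 3, by an amount that was not computed. Retention of such introns in the predicted exons could be read from the genome sequence. Such retention, a real scarcity of these introns and the effect of the bin limits all stay open, and no biological explanation was tested.

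Gene-dense scaffolds had shorter introns. Across the 63 scaffolds of at least 50 kb, density and median intron length had a Pearson r of -0.66 (permutation p = 1e-05; 2e-05 after Benjamini-Hochberg adjustment over the 2 relations computed) and a Spearman rho of -0.68 (permutation p = 1e-05), where 1e-05 is the smallest p the permutations can give. Without the 2 scaffolds farthest from the median density r was -0.65, and over the 44 scaffolds with at least 50 genes it was -0.65. Introns are part of the span that density is measured on, which alone ties these quantities together. Density and mean exon number had a Pearson r of -0.30 (permutation p = 0.0168 raw and adjusted) and a Spearman rho of -0.18 (permutation p = 0.158), and without the 2 farthest scaffolds r was -0.11, so this relation rests on those scaffolds. They were scaffold00132 with 23.5 genes per 100 kb, 8.05 exons per gene and a median intron of 184 bases, and scaffold00844 with 21.4 genes per 100 kb, 8.11 exons per gene and a median intron of 198 bases.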
